A study of Rattus norvegicus with 6 samples.

How the data were processed

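The series holds 6 Illumina rat expression BeadChip arrays of trigeminal nerve RNA, 1 for each combination of 3 strains (BDIX, BDIV and the congenic BDIX.BDIV-Mss4a) and 2 sexes. Per the labels, RNA was extracted with Trizol from pooled nerves of untreated rats aged 85 days and biotin-labelled cRNA was made with an Ambion kit. Groups were taken from the sample titles. Every sample is a separate pool, so strain comparisons rest on 1 male and 1 female pool per strain, and strain cannot be told apart from any hybridisation batch, since no batch is labelled.

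The authors deposited a table of signal intensity and detection p-value for each array, per the file headers, and a table of processed values. BeadStudio 3.0 is named in the submitters' processing notes. The deposited signal intensity is on a linear scale without background subtraction, with a lowest value of 56.3 on the congenic male array. The deposited detection p-value moved in steps that imply 825 negative control probes. For 623 probes the detection p lay between these steps, as an average over bead types would. The processed intensity values that the authors deposited were a straight line of the signal on each array, with slopes of 0.993 and 0.977 on the congenic male and female arrays, 0.482 and 0.453 on the BDIX arrays and 0.326 and 0.361 on the BDIV arrays. Their medians were 13.9, 14.7, 15.5, 15.0, 19.9 and 16.8 in the same order. They are thus linear, with a level subtracted and a scale applied per array. The subtracted level was 85.2 and 78.7 on the congenic arrays, 55.3 and 47.5 on the BDIX arrays and 35.5 and 49.8 on the BDIV arrays, against background means of 84.7, 80.8, 63.4, 57.9, 66.3 and 65.8, so part of the background was left in on the BDIX and BDIV arrays. How level and scale were chosen is not given in the sources used here. Of 21791 probes, 242 in 121 adjacent pairs had their values exchanged between the 2 tables and were left out, which leaves 21549.

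Gene names came from the platform annotation. Of 21791 probes 13387 had 1 gene symbol, 0 had several and 8404 had none. By gene number 13349 were matched to the reference gene table of the GRCr8 assembly and 5 more by accession, 4 symbols were updated and 33 kept the platform symbol without a match. The genome build behind the probes is not given in the sources used here, so positions served only to order neighbouring genes and no coordinates are printed. Probe sequences were not analysed here, and a sequence difference between strains under a probe cannot be told from a difference in transcript level.

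Background was corrected by a normal-exponential model whose background mean and SD were estimated from the detection p of the probes without an averaged detection p (limma 3.58.1 in R 4.3.3), an offset of 16 was added, arrays were quantile normalised and log2 taken. Background means ranged from 57.9 on the BDIX female to 84.7 on the congenic male array. Probes with a detection p under 0.01 on at least 2 of 6 arrays were tested, 10484 in number. The number of arrays limits the precision. A limma model with strain and sex was fitted to all 6 arrays, with 2 residual degrees of freedom and 5.28 prior degrees of freedom from moderation with an intensity trend. Its residual holds any difference of the sex effect between strains. Calls are Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene comes from limma. Several probes of a gene were kept apart in the counts (16 genes had several tested probes, with 0 genes called in both directions), and 1 probe per gene, that of the highest mean, entered the lists. The steps were tested on simulated data of 10484 probes. With 100 probes planted at a log2 difference of 1 and 100 at 2, male versus female recovered 88 and 100 with 14 false calls, and congenic versus BDIX 56 and 100 with 11 false calls.

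Where a gene was not detected on any array of a group, the fold is given as "at least". It sets the mean of the brighter group against a floor, the mean over the other group's arrays of the higher of the lowest detected value and the probe's own value. Differences without such a bound are log2 values, and SE is the standard error from the fit. Where a log2 difference stands beside a bound, it takes in values at background, and only the bound holds as a size.

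The comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Genes were named as the 12 largest differences in each direction among probes past the threshold with one sign in every matched pair, as the 10 smallest p where fewer than 10 passed, and as up to 4 members with the smallest p of each list described. Sex chromosome genes were named as a label check, and for effects by sex the 10 largest gaps in each direction among probes detected on at least 2 of 4 arrays. The 32 lists covered cells of the nerve (myelinating Schwann cell, Schwann lineage, sensory neuron and axon, satellite glia, fibroblast and extracellular matrix, perineurial, endothelial, pericyte), cells from outside it (macrophage, lymphocyte and mast cell, adipocyte, skeletal muscle, erythrocyte, central nervous system glia, pituitary, bone and cartilage) and processes (interferon response, antigen presentation, complement, sterol biosynthesis, fatty acid synthesis, DNA repair, the ErbB and Ras pathway, proliferation, sex steroid response, immediate early genes, heat shock, xenobiotic defence, hypoxia and glycolysis, mitochondrial respiratory chain, ribosomal protein, sex chromosome). A list of neutrophil and bone marrow genes was added later. An alias was used to find a list member only where the member's name is not itself the symbol of another gene. This rule was added after the list results had been seen, because titin (Ttn) of the skeletal muscle list had been read as Dbi through an alias. Without Dbi the skeletal muscle list has 6 tested genes, and camera no longer called it or the sensory neuron list for sex. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, whose p asks whether the genes of a list move on balance in one direction. The estimated correlation and fry rest on 2 residual degrees of freedom and have little power.

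Effects by sex had no residual and were read by a size rule of 1 log2 unit, with list medians placed among 10000 random lists matched on mean intensity. Where an array was below detection, its value was set to whichever of its lowest detected level and its lowest level made the gap smaller, and the gap is given as a least gap. Shared BDIX arrays were allowed for by simulating unchanged strains. Positions of calls were tested with 10000 permutations. Alternatives covered background correction, scaling, the authors' processed values, the detection filter, moderation, the covariate, the arrays fitted and each array left out. Added once the data were at hand were background from all probes, keeping the 242 exchanged probes or leaving out those with an averaged detection p, the positions of calls shared with BDIV, cyclic loess and left-out arrays for the gene lists, alternatives for the probes called in both strains, the fit without probes of cells from outside the nerve, and the list of neutrophil and marrow genes. In a fit without 1 array the lone array of that strain is assumed to vary like the others.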

Results

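Transcript levels were measured in the trigeminal nerve of untreated rats aged 85 days from 3 inbred strains. Ethylnitrosourea, an alkylating carcinogen, induces malignant schwannomas of this nerve in BDIX rats, whereas BDIV rats are resistant. The congenic strain BDIX.BDIV-Mss4a carries the BDIV segment Mss4a, one of the loci linked to this resistance, on the BDIX background and is called congenic here. RNA from pooled nerves of each strain and sex was hybridised to 1 Illumina rat expression BeadChip array, which gave 6 arrays, 2 per strain and 3 per sex. Each strain and sex therefore had a single measurement, and the number of animals in a pool was not given in the sources used here. The p-values measure the spread between these 6 pools after strain and sex are taken out.

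The arrays differed in brightness. The upper quartile of the signal over background was 2.92 on the congenic male array and 3.01 on the congenic female array. On the BDIX arrays it was 6.24 in the male and 6.93 in the female, and on the BDIV arrays 7.79 and 7.81. Probes detected at a p under 0.01 numbered 8796 (40.4%) on the congenic male, 8949 (41.1%) on the congenic female, 9770 (44.8%) on the BDIX male, 10307 (47.3%) on the BDIX female, 9991 (45.8%) on the BDIV male and 10167 (46.7%) on the BDIV female array. Eif2s3, Usp9x and Ddx3x, genes on the X chromosome that escape inactivation in part, were lower in the male than in the female pool in 3 of 3 strains, with male minus female differences of -0.68 ± 0.18, -0.43 ± 0.18 and -0.23 ± 0.19 (log2 ± SE). None of these 3 passed the test for sex, and Y-linked genes and Xist were not analysed here. The log2 values of the male and female pools differed across probes with an SD of 0.52 in BDIX, 0.45 in the congenic and 0.21 in BDIV, so the residual spread came mostly from the BDIX and congenic pairs.

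The comparison of BDIV with BDIX asks how the nerve of a resistant strain differs from that of a susceptible one before any carcinogen is given. In BDIV 15 of 19 sensory neuron genes were higher, and 8 of 12 myelinating Schwann cell, 11 of 18 matrix and 3 of 5 erythrocyte genes were lower. As lists these passed camera at a preset correlation only (adjusted p = 0.784 with an estimated correlation). No dissection record is given in the sources used here. Here and in the comparisons below, unequal shares of cell types or tissue in the pools cannot be told from changes within cells. Nrg1, the axonal growth factor that signals to Schwann cells through ErbB receptors, was higher by 2.78 ± 0.24 (log2 ± SE, 2 arrays per strain, adjusted p = 0.00195), while its receptor genes Erbb3 (-1.62 ± 0.21, adjusted p = 0.00452) and Erbb2 (-1.08 ± 0.22, adjusted p = 0.014) were lower. Erbb2 lost its call without the BDIV male (adjusted p = 0.112) or the BDIV female array (adjusted p = 0.131). Sox10, the transcription factor of the Schwann cell lineage, fell by 1.75 ± 0.17 (adjusted p = 0.00256). The Schwann lineage list as a whole was not lower, with 3 of 13 genes lower, 1 higher and a median of 0.11. The alpha-globin transcript Hba-a3 fell by 4.95 ± 0.23 (adjusted p = 3.43e-04). The probe of Rpl30, a gene for a protein of the large ribosomal subunit, read higher by 5.66 ± 0.29 (adjusted p = 3.88e-04). The ribosomal protein list, which does not hold Rpl30, had a median of 0.23. A strain difference in sequence under the Rpl30 probe cannot be told from a change in transcript level. The same limit holds for the other probes, those of Plekhh1 and Fam151b below among them. Of 10484 probes tested with limma, 2867 passed an adjusted p of 0.05, 1440 higher and 1427 lower in BDIV, and 1572 of them differed by more than 2-fold. The calls covered 2184 named genes. All 2867 probes had the same sign in males and in females. A difference between the sexes enters the residual of the fit, so probes of opposite sign could hardly be called.

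The 12 largest increases in BDIV also held Plekhh1, at least 7.24-fold higher and not detected on the BDIX arrays, Tlcd3b (3.29), Pafah1b1 (3.26), a regulator of the dynein motor, and the class I histocompatibility gene RT1-CE16, at least 4.98-fold higher. Gpx2, a glutathione peroxidase, rose by 3.08, the neuropeptide somatostatin (Sst) by 2.80, the RNA-binding protein Celf6 by 2.79 and Commd6 by 2.71. The secreted lectin Reg3a was at least 5.01-fold higher. Rhoa, a small GTPase, rose by 2.68 ± 0.82, but its call was lost without the BDIX female (adjusted p = 0.155) or the BDIV male array (adjusted p = 0.14). Among the 12 largest decreases, the defensin genes Defa5 (-4.10, at least 14.7-fold lower), RatNP-3b (-4.03) and Np4 (-3.15, at least 5.31-fold lower) stood with S100a8 (-3.96), a calcium-binding protein of neutrophils. Np4 lost its call without the BDIX male (adjusted p = 0.0586), the BDIX female (adjusted p = 0.0511) or the BDIV male array (adjusted p = 0.195). Erythroid transcripts were Lgals5 (-3.85), Hemgn (at least 6.06-fold lower), Alas2 (at least 4.83-fold lower), the first enzyme of haem synthesis in red cells, and Hbb-b1 (-2.86). Fam151b was at least 12.4-fold lower, the lipoxygenase Alox15 at least 6.78-fold lower, and prolactin (Prl) fell by 4.05 ± 0.72. The other 22 of these 24 genes kept an adjusted p under 0.05 whichever array was left out, but with the authors' processed values 16 of the 24 kept it and 8 did not.

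Among the gene lists, 15 of 19 sensory neuron and axon genes were higher in BDIV (list median 1.14) and none lower. The neurotrophin receptor Ntrk2 rose by 1.75 ± 0.19 and the neuronal ubiquitin hydrolase Uchl1 by 1.69 ± 0.22, and 16 passed when adjusted over the list alone. Of 12 myelinating Schwann cell genes 8 were lower (median -1.14, 10 adjusted over the list alone), among them Cnp (-1.91 ± 0.21), an enzyme of non-compact myelin, Gldn (-1.93 ± 0.25), which organises nodes of Ranvier, and myelin basic protein Mbp (-1.59 ± 0.25). Of 18 fibroblast and extracellular matrix genes 11 were lower (median -1.07, 11 adjusted over the list alone), including the collagen V genes Col5a2 (-2.05 ± 0.19) and Col5a1 (-1.79 ± 0.18). Of 5 erythrocyte genes 3 were lower (median -2.29, 5 adjusted over the list alone). A list of neutrophil and bone marrow genes, written after values had been seen and sharing Ahsp, Alas2 and Epb42 with the erythrocyte list, had 11 of 19 lower and 1 higher (median -1.92, unadjusted camera p = 0.372 with an estimated correlation). Of 19 mitochondrial respiratory chain genes 6 were higher (median 0.60, 7 adjusted over the list alone), with Cox5a at 1.48 ± 0.29. In the proliferation list 2 of 16 were lower (median -0.64, 2 adjusted over the list alone), the replication helicase genes Mcm6 and Mcm2. In the immediate early list 3 of 15 were lower (median -0.49, 3 adjusted over the list alone), led by Egr1 (-1.48 ± 0.20). As 1427 of all 10484 probes were called lower, 2 of 16 is no excess and 3 of 15 at most a slight one. The camera test called these 7 of 32 lists, with adjusted p of 2.68e-07 for sensory neuron, 1.85e-05 for fibroblast, 5.42e-05 for myelinating Schwann cell, 8.34e-04 for mitochondrial, 0.00842 for erythrocyte, 0.0225 for proliferation and 0.0452 for immediate early genes. None held with a correlation between genes estimated from these arrays (adjusted p = 0.784 with an estimated correlation for the first 5, 0.799 for proliferation and immediate early), and fry called 0 of 32. With 2 residual degrees of freedom both tests have little power, here and below, so a call lost in them leaves a list undecided. The estimated correlation was 0.517 for sensory neuron, 0.485 for erythrocyte, 0.444 for myelinating Schwann cell and 0.276 for immediate early genes. It was 0.261 for fibroblast, 0.178 for proliferation and 0.111 for mitochondrial genes. All lay above the preset 0.01, so the camera p at the preset correlation may be too small. Without the BDIV female array Mbp had an adjusted p of 0.0614, Egr1 of 0.0525, Cox5a of 0.122, Mcm6 of 0.0684 and Mcm2 of 0.305, and Mcm6 and Mcm2 also missed the threshold without the BDIV male array (0.157 and 0.134). The proliferation list lost its call without the BDIV male (0.421) or the BDIX male array (0.185), and the immediate early list without the BDIV female (0.201) or the BDIX female array (0.0751). Of 90 called list members that the naming rule selects, 23 kept an adjusted p under 0.05 whichever array was left out and 67 did not, with 24 kept without the BDIV female array and 38 with the authors' processed values.

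Genes of alkylation damage and DNA repair, which act on the lesions that ethylnitrosourea makes, did not differ as a list between BDIV and BDIX (median 0.06, camera adjusted p = 0.89). Of 16 tested, Alkbh3, a direct reversal enzyme, was higher by 0.99 ± 0.19 (adjusted p = 0.0115), and the single-strand break repair gene Xrcc1 (-0.71 ± 0.19, adjusted p = 0.0292) and the ligase gene Lig1 (-0.75 ± 0.20, adjusted p = 0.0308) were lower, 3 genes in all when adjusted over the list alone as well. Without the BDIV female array their adjusted p were 0.171, 0.329 and 0.324, and without the BDIV male array 0.054, 0.126 and 0.132. Xrcc1 and Lig1 also missed the threshold without the congenic male (0.0591 and 0.0504) or the congenic female array (0.059 and 0.0504). Mgmt, the O6-alkylguanine transferase, had a difference of 1.07 ± 0.34 that missed the threshold (adjusted p = 0.0529). Outside the called lists, the endothelial gene Vwf fell by 1.97 ± 0.18, the interferon-induced Mx2 rose by 1.85 ± 0.18, the class I gene RT1-A3 rose by 2.20 ± 0.22, and the phase I and glutathione synthesis genes Cyp1b1 (-1.57 ± 0.19) and Gclc (-1.52 ± 0.21) fell. Of the 21 xenobiotic and oxidative defence genes 2 were higher and 4 lower. The interferon response list had 3 of 11 higher and 1 lower, and the antigen presentation list 2 of 19 higher and 1 lower. Of all probes 27.3% were called, so these counts, and that of the DNA repair genes, do not set the lists apart.

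The number of calls between BDIV and BDIX depended on single arrays, while none of the calls above changed sign when an array was left out. Leaving out the BDIX male array gave 4404 calls, the BDIV male array 1273 and the BDIV female array 378. Under median scaling 3392 probes were called, 63.0% of them higher in BDIV, against 50.2% in the fit above, with the median of all probes at 0.08. The neuronal, Schwann cell and matrix lists kept their direction and camera call under median scaling, cyclic loess and the authors' processed values, all at the preset correlation. With an estimated correlation (adjusted p = 0.784) and with fry (adjusted p = 0.111) none of the 3 was called.

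**Figure D1:**
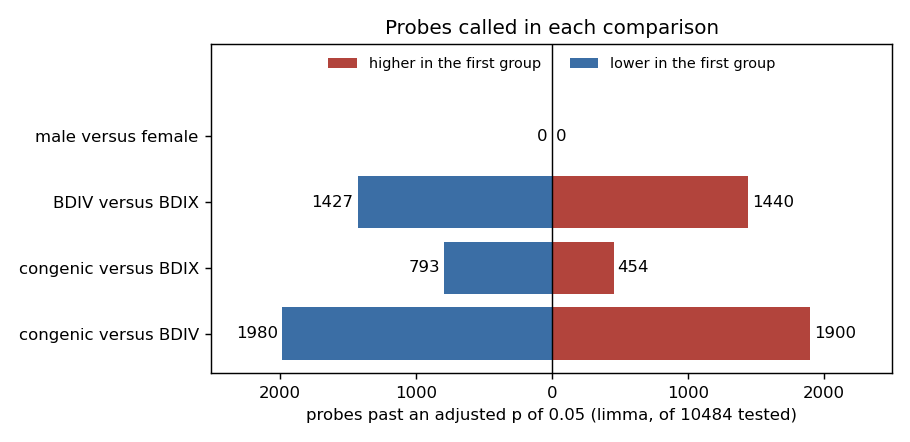
Number of probes past an adjusted p of 0.05 (limma, 10484 probes tested) in each comparison, with bars to the right for probes higher and to the left for probes lower in the first group named. BDIV versus BDIX had 1440 higher and 1427 lower, congenic versus BDIX 454 and 793, congenic versus BDIV 1900 and 1980, and male versus female 0 and 0.

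The comparison of the congenic strain with BDIX asks what the introgressed Mss4a segment changes. In the congenic 8 of 13 sterol synthesis and 5 of 12 myelinating Schwann cell genes were lower. As lists these passed camera at a preset correlation only (adjusted p = 0.856 and 0.907 with an estimated correlation). Idi1, an isomerase of the mevalonate pathway, fell by 2.07 ± 0.17 (log2 ± SE, 2 arrays per strain, adjusted p = 0.0056), and Mbp fell by 2.17 ± 0.25 (adjusted p = 0.00879). Plekhh1 rose by 3.55 ± 0.22 (adjusted p = 0.00225) to the level seen in BDIV, at least 7.53-fold above the BDIX arrays, which did not detect it. Of 10484 probes 1247 were called, 454 higher and 793 lower, in 898 named genes, and 771 of them differed by more than 2-fold. All 1247 had the same sign in males and in females, which the residual of the fit again makes near certain.

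Of the 12 largest increases in the congenic, 7 were genes known from nasal, oral or airway epithelium and its glands. Bpifa1, a secreted airway protein, rose by 5.05 ± 0.75 (at least 23.7-fold), the lipase Lipf by 4.31 ± 0.59 (at least 10.7-fold), the von Ebner gland protein Vegp2 by 3.82 ± 0.73 (at least 8.49-fold), the lipocalin Lcn1 by 3.18 ± 0.60, and the olfactory and airway cytochrome P450 genes Cyp2g1, by at least 5.86-fold, and Cyp2a3 and Cyp2f4, each by at least 2.42-fold. This grouping was made after their values were seen, and no gene list or enrichment test covers it. Bpifa1 had a log2 intensity of 8.34 on the congenic male and 11.81 on the congenic female array and at most 5.28 on the other 4. Vegp2 had the opposite order, 10.26 in the male and 6.93 in the female. The other increases were Fmod (2.24 ± 0.25), a collagen-binding proteoglycan, Aplp1 (2.22 ± 0.30), a relative of the amyloid precursor protein, Gpx2 (2.14 ± 0.28) and the zinc transporter gene Slc39a12 (at least 3.50-fold), besides Plekhh1. The largest decreases were in the cartilage genes Cnmd (-2.88 ± 0.19) and Epyc (-2.69 ± 0.41), the kinesin gene Kif5b (-2.40), Tmprss5 (-2.31), Purb (-2.31), the caveolae gene Cav1 (-2.28), the vesicle transport gene Bet1 (-2.26), Sh3bgrl1 (-2.13), and Cdc25b and Csnk1a1, at least 2.09-fold and 1.95-fold lower. Slc39a12 lost its call without the congenic female (adjusted p = 0.0709) or the BDIX female array (adjusted p = 0.0506) and Sh3bgrl1 without the congenic female array (adjusted p = 0.0779). The other 22 of these 24 genes kept an adjusted p under 0.05 whichever array was left out.

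Of 13 sterol biosynthesis genes 8 were lower in the congenic and none higher (median -0.97, 11 adjusted over the list alone), including the farnesyl diphosphate synthase gene Fdps (-1.68 ± 0.20) and the lanosterol demethylase gene Cyp51 (-1.79 ± 0.22). Myelin is rich in cholesterol, and of 12 myelinating Schwann cell genes 5 were lower (median -0.92, 7 adjusted over the list alone). Besides Mbp these included Pllp (-1.83 ± 0.20), a myelin proteolipid, and Ugt8 (-1.82 ± 0.20), the enzyme that makes galactocerebroside. Of 11 fatty acid and lipid synthesis genes 3 were lower (median -0.65, 5 adjusted over the list alone), namely Acly (-1.19 ± 0.18), Scd (-1.15 ± 0.18) and Fads1 (-1.39 ± 0.22). Of 12 heat shock and unfolded protein genes 3 were lower (median -0.37, 4 adjusted over the list alone), namely Creld2 (-1.83 ± 0.26), Hsp90aa1 (-1.66 ± 0.29) and Hsp90b1 (-1.07 ± 0.25). Camera called these 4 of 32 lists, with adjusted p of 4.94e-07 for sterol, 0.00334 for myelinating Schwann cell, 0.0368 for fatty acid and 0.0441 for heat shock genes. None was called with an estimated correlation (adjusted p = 0.856 with an estimated correlation for sterol and 0.907 for the other 3), and fry called 0 of 32. Under median scaling the sterol list kept its camera call (median -1.57, adjusted p = 1.10e-05). The myelinating Schwann cell (median -1.196, adjusted p = 0.155), fatty acid (-0.956, 0.155) and heat shock lists (-0.805, 0.0615) lost theirs. The median of all tested probes was then -0.52. The fatty acid list was also lost without the congenic male (0.0558), the congenic female (0.0773) or the BDIX female array (0.115), and the heat shock list without the congenic male (0.098), the congenic female (0.0862) or the BDIX male array (0.103). Acly and Scd had adjusted p of 0.0627 and 0.0553 without the congenic male array and 0.0762 and 0.115 without the congenic female array, Fads1 had 0.0508 without the congenic male, and Hsp90aa1 and Hsp90b1 had 0.0703 and 0.334 without the congenic female. Of 47 called list members that the naming rule selects, 15 kept their call whichever array was left out and 32 did not, with 18 kept without the congenic female array.

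None of the 16 alkylation damage and DNA repair genes was called between the congenic and BDIX by limma (0 adjusted over the list alone too), the smallest adjusted p being 0.0859 for the glycosylase gene Mpg at 0.92 ± 0.31. Nrg1 fell by 1.13 ± 0.24 (adjusted p = 0.0309), at least 1.23-fold, in the congenic, the opposite direction to BDIV, and lost its call without the congenic female array (adjusted p = 0.131). The haem synthesis gene Alas2 differed by -1.96 ± 0.29, and the skeletal muscle genes Acta1 and Tnnc2 were higher by 1.80 ± 0.31 and 1.83 ± 0.30. In the matrix list Fmod rose while the fibrillar collagen genes Col1a1 (-2.05 ± 0.28) and Col3a1 (-1.60 ± 0.21) fell. No call held with the authors' processed values (0 probes past the threshold with limma, 3190 at an unadjusted p under 0.05).

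The count for the congenic depended on single arrays and on the scaling. The BDIV arrays do not enter the congenic minus BDIX difference, only the estimate of its spread. A change of the count without them is therefore one of the spread. Leaving out 1 array gave 691 calls without the congenic male, 581 without the congenic female, 3176 without the BDIX male, 2140 without the BDIX female, and 782 without either BDIV array. Median scaling called 4316 probes, 103 higher and 4213 lower, a share of 2.39% higher against 36.4% in the fit above. The median of all tested probes was then -0.52, so that most of them stood below BDIX on the dimmer congenic arrays, and the changes given here are relative to such a shift. Median scaling aligns the median over detected and undetected probes. At most 47.3% were detected on an array, so that median lay at background and the shift need not be one of transcript levels.

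**Figure D2:**
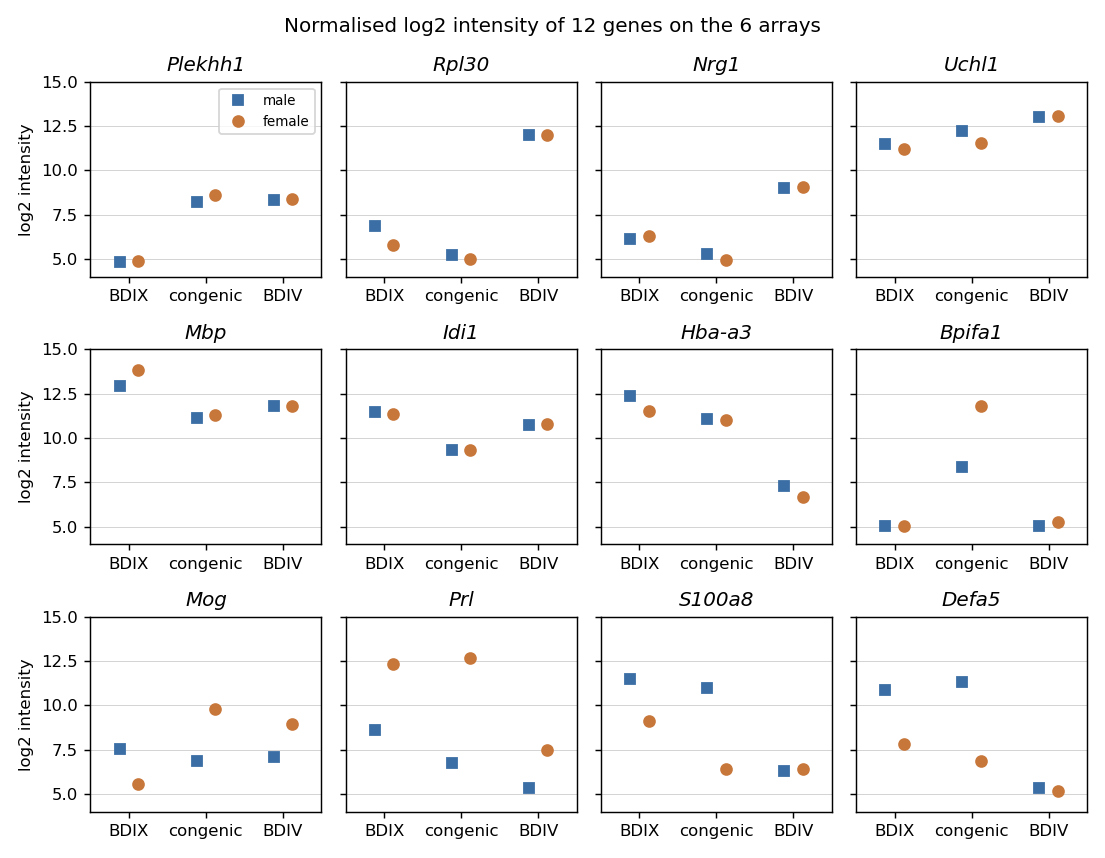
Normalised log2 intensity of 12 genes on the 6 arrays, with strain on the horizontal axis, squares for male and circles for female pools, and 1 array per point. Plekhh1 was near the floor in BDIX and similar in congenic and BDIV, Nrg1 was highest in BDIV, and Prl was higher in the female pool of 3 of 3 strains.

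Whether the congenic moved towards its donor was asked by setting both differences from BDIX side by side. Across 10484 probes, which are not independent replicates, the congenic minus BDIX and BDIV minus BDIX differences correlated with a Pearson r of 0.26. Unchanged strains set against the same BDIX arrays gave a mean r of 0.50 in 100 simulated draws. The covariance was 0.114 against 0.03 in the simulation, a difference of 0.084. The simulation gave all arrays the same spread for a probe. The BDIX pair differed more, with an SD of 0.52 across probes between its pools against 0.21 in BDIV. The simulated covariance may therefore be too low and the difference of 0.084 too large. The sign was shared by 58.4% of probes, against 66.6% simulated. Of 428 probes called in both comparisons, 364 had the same direction, 156 higher and 208 lower, and 64 the opposite. Independent lists of these sizes would share 62.4 higher and 107.9 lower, but such lists ignore the shared BDIX arrays, and the simulated strains carry no changes, so neither is a fair comparator for the 364. With 2 BDIX arrays the controls could not be split, and how far the shared calls come from the shared arrays stays open. The count with the same direction was 210 without the congenic male, 186 without the congenic female, 1634 without the BDIX male, 703 without the BDIX female, 139 without the BDIV male and 40 without the BDIV female array. Gpx2 and Plekhh1 rose in both strains and Mbp, Idi1 and Alas2 fell in both, while Nrg1 rose in BDIV and fell in the congenic. The call of Idi1 in BDIV (-0.66) was lost without the congenic male (adjusted p = 0.0849), the congenic female (0.0848), the BDIV male (0.225) or the BDIV female array (0.234).

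A congenic strain is expected to differ in sequence from its background mainly within the introgressed segment, so the positions of the called genes were examined in the order of the GRCr8 rat assembly. Where Mss4a lies was not used. Of 7771 tested genes with a position, 893 were called between congenic and BDIX. The chromosome that carries Bpifa1, Map1a and Fgf7 held 92 of them among its 572 tested genes, where 65.7 were expected (one-sided permutation, adjusted p = 0.0147 over chromosomes). The fullest window of 50 neighbouring genes lay on the same chromosome, from Fibin to Fgf7, and held 15 calls, including the Ras pathway inhibitor gene Spred1, the kinase gene Eif2ak4 and Map1a. A window as full arose in permuted orders with p = 0.2687 (one-sided permutation). Among the 100 genes with the smallest p, the fullest window ran from Nsfl1c to Dlgap4 on that chromosome and held 6 genes, Bpifa1 among them (permutation p = 0.0257), but the excess on the chromosome as a whole was then not past the threshold (adjusted p = 0.3465). Calls shared with BDIV in direction and not separating the congenic from BDIV numbered 239 positioned genes and did not gather (permutation p = 0.9017 for the fullest window, smallest adjusted p = 0.6761 over chromosomes).

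The comparison of the congenic strain with BDIV covers the genome outside the shared segment. Of 19 sensory neuron genes 12 were lower in the congenic than in BDIV. After quantile normalisation 5 of 5 erythrocyte, 4 of 8 endothelial and 7 of 15 immediate early genes were higher, and of 18 matrix genes 10 were higher and 3 lower. As lists these passed camera at a preset correlation only (adjusted p = 0.875 with an estimated correlation). Nrg1 fell by 3.91 ± 0.24 (log2 ± SE, 2 arrays per strain, adjusted p = 4.12e-04), at least 8.43-fold, and the neurofilament gene Nefh by 2.20 ± 0.30 (adjusted p = 0.00323). Hba-a3 rose by 4.05 ± 0.23 (adjusted p = 3.91e-04). Of 10484 probes 3880 were called, 1900 higher and 1980 lower in the congenic, in 2815 named genes, and 2033 differed by more than 2-fold. Each of the 3880 had the same sign in males and in females, near certain here too for a call from this fit.

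The largest increases over BDIV again included Bpifa1 (at least 24.1-fold), Lipf (at least 10.8-fold), Vegp2 (at least 8.60-fold), Cyp2g1 (at least 5.93-fold) and Lcn1 (3.26). Others were Fam151b (at least 9.0-fold), Defa5 (at least 12.1-fold), Prl (3.31 ± 0.72), Lgals5 (3.30 ± 0.23), the interferon-induced GTPase gene Ifi47 (at least 4.84-fold) and the clock gene Nr1d1 (2.92 ± 0.21). The largest decreases were Rpl30 (at least 67.0-fold), Pafah1b1 (-3.68), Commd6 (at least 6.26-fold), Tmem243 (at least 4.87-fold), Sst (-3.29), Plcxd3 (-3.29), the proteasome chaperone gene Psmd5 (at least 7.89-fold), Lgi2 (-3.13), RT1-CE16 (at least 3.70-fold), the polarity gene Lin7b (at least 5.70-fold) and the amino acid transporter gene Slc3a1 (-2.91). All 24 genes of the largest changes kept an adjusted p under 0.05 whichever array was left out and under median scaling and cyclic loess, but with the authors' processed values 18 kept it and 6 did not.

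The 12 lower sensory neuron genes (list median -0.92, 13 adjusted over the list alone) included Stmn2 (-1.86 ± 0.21), Ntrk2 (-1.70 ± 0.19) and Ntrk3 (-1.43 ± 0.22). All 5 erythrocyte genes were higher (median 1.57, 5 adjusted over the list alone), and of the 19 marrow genes, which include 3 of these 5, 9 were higher (median 1.99, 17 adjusted over the list alone, unadjusted camera p = 0.391 with an estimated correlation). Also higher were 4 of 8 endothelial genes (median 0.73, 5 adjusted over the list alone), led by Vwf (2.34 ± 0.18) and Tie1 (1.73 ± 0.21), and 7 of 15 immediate early genes (median 0.52, 7 adjusted over the list alone), led by Junb (1.62 ± 0.19) and Fos (1.98 ± 0.34). Of 18 fibroblast and matrix genes 10 were higher and 3 lower (median 0.91, 11 higher and 3 lower adjusted over the list alone), with Fmod at 2.54 ± 0.25 and Sparc at 1.81 ± 0.21. Lower parts were 6 of 19 mitochondrial genes (median -0.40, 6 adjusted over the list alone), 4 of 13 sterol genes (median -0.48, 5 adjusted over the list alone), with Fdps at -1.82 ± 0.20, and 4 of 13 hypoxia and glycolysis genes (median -0.41, 4 adjusted over the list alone), with the enolase gene Eno1 at -2.09 ± 0.22. Camera called these 8 of 32 lists, with adjusted p of 4.71e-05 for sensory neuron, 0.0189 for erythrocyte, endothelial, immediate early and mitochondrial, 0.0266 for fibroblast and sterol, and 0.0478 for hypoxia genes. All 8 were lost with a correlation taken from the data (adjusted p = 0.875 with an estimated correlation for each), and fry called 0 of 32. Leaving out 1 array ended the call of the fibroblast list (without the congenic female, adjusted p = 0.17), the immediate early list (without the BDIV female, 0.0508), the mitochondrial list (without the BDIV female, 0.0757, or the congenic male, 0.0815), the sterol list (without the BDIV male, 0.0597, or the congenic female, 0.137) and the hypoxia list (without the BDIV male, 0.161, the congenic female, 0.0741, or the congenic male, 0.177). Of 105 called list members that the naming rule selects, 43 kept their call whichever array was left out and 62 did not, with 52 kept without the BDIV female array and 60 with the authors' processed values.

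Sox10 (1.33 ± 0.17) and Erbb3 (1.46 ± 0.21) were higher in the congenic than in BDIV, as were Gclc (1.91 ± 0.21), Cyp1b1 (1.54 ± 0.19) and catalase, Cat (1.60 ± 0.21). The last 3 belong to the 21 xenobiotic and oxidative defence genes, of which 7 were higher and 4 lower (median 0.11, camera adjusted p = 0.568). Leaving out 1 array gave 2432 calls without the congenic male, 2125 without the congenic female, 1498 without the BDIV male and 1070 without the BDIV female. Median scaling called 5913 probes, 498 higher and 5415 lower, a share of 8.42% higher where the fit above had 1900 higher and 1980 lower, with the median of all probes at -0.64 and 443 calls changed in sign. Under median scaling the medians of the endothelial (-0.08) and immediate early lists (-0.26) turned below 0 while lying above that shift, and the erythrocyte and fibroblast lists stayed higher (1.02 and 0.21).

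**Figure D3:**
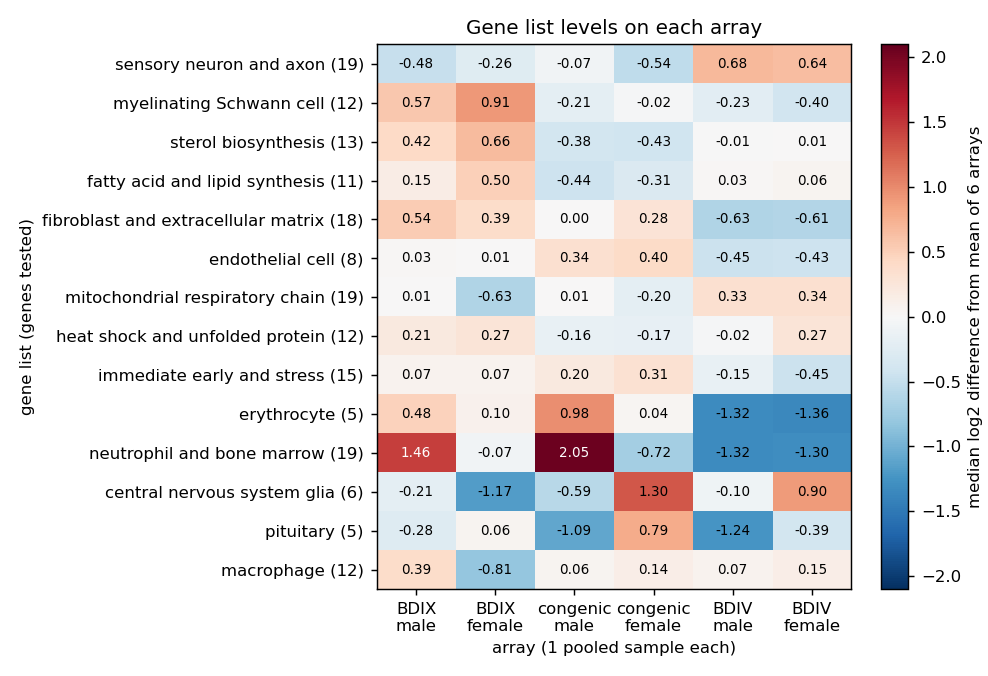
Median log2 difference from each gene's mean over the 6 arrays for 14 gene lists, as a heat map with lists in rows of the plot (genes tested in brackets) and 1 array per column. Sensory neuron genes stood at 0.68 and 0.64 on the BDIV arrays, sterol genes at -0.38 and -0.43 on the congenic arrays, and neutrophil and marrow genes at 1.46 and 2.05 on the BDIX and congenic male arrays.

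Male and female pools were compared within strains, the study's title concerning tumour suppression that is biased by sex. Prl, the pituitary hormone prolactin, was lower in the male pool of 3 of 3 strains, by a mean of -3.94 ± 0.59 (log2 ± SE, 3 arrays per sex), with pair values of -3.74 in BDIX and -5.91 in the congenic. The BDIV male array did not detect it, so the mean takes in a value at background. Cldn11, a tight junction protein of myelin sheaths in the central nervous system, differed by -1.09 ± 0.17. Slfn4 (0.90 ± 0.17), the chemokine Cxcl13 (0.83 ± 0.18), Hbb-b1 (0.61 ± 0.14), Lgals5 (0.78 ± 0.19), the cytokine signalling inhibitor Socs2 (0.80 ± 0.20) and Mmp23 (0.79 ± 0.20) had higher values in males of each strain, with Socs2 detected on 5 and Mmp23 on 4 of the 6 arrays. Zbp1 (at least 1.45-fold higher in males) and Atxn3 (at least 1.26-fold lower) complete the 10 genes with the smallest p and one sign in the 3 strains. None of them passed the threshold (adjusted p = 0.959 for each). By limma 0 of 10484 probes were called, with 321 at an unadjusted p under 0.05. With strain left out of the model limma again called 0, with 18 at an unadjusted p under 0.05. For a single gene, 3 arrays against 3 allow no exact permutation p below 0.1.

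Leaving out 1 array gave calls for sex. Without the congenic male or the congenic female array Prl alone was called (-2.95 in both fits, adjusted p = 0.0042 and 0.00461). Without the BDIX male array 13 probes and without the BDIX female array 11 were called, all lower in males, and they included the myelin and oligodendrocyte genes Mog (-2.36), Mobp (-2.61) and Olig1 (-2.17), the astrocyte gene Gfap (-1.47), and Cldn11, Ermn, S1pr5, Pomc, Fabp7, Itih3 and Ppp1r14a. Without either BDIV array 8 were called, 7 higher in males, namely the neutrophil genes Defa5 (3.76), RatNP-3b (4.34), Np4 (3.92), S100a8 (3.50) and Ceacam4 (2.36), with Nkg7 (2.04) and the erythroid chaperone gene Ahsp (2.72), and Prl was lower (-4.83). With the 68 probes of the neutrophil, blood, pituitary and other lists of cells from outside the nerve left out, 0 were called by limma and 313 had an unadjusted p under 0.05.

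No member of any fixed list passed the threshold for sex over all probes, and adjusted over the list alone 1 pituitary gene and 1 sex chromosome gene were lower in males. Camera called 8 of 32 lists on small shifts. Antigen presentation (median 0.22, 18 of 19 positive, adjusted p = 7.12e-04), proliferation (0.32, 5.58e-04), ribosomal protein (0.14, 0.00536), erythrocyte (0.36, 0.00794), complement and acute inflammation (0.20, 0.00794), and mitochondrial genes (0.19, 0.00794) had higher values in males over the 3 strains. By strain the antigen presentation median was 0.71 in BDIX, -0.01 in BDIV and 0.02 in the congenic, the ribosomal median 0.63, -0.06 and -0.06, with 7 of 30 members higher in congenic males, and the complement median 0.54, 0.01 and -0.01. Proliferation stood at 0.46, 0.00 and 0.49, mitochondrial genes at 0.58, -0.02 and 0.16 and erythrocyte genes at 0.08, 0.06 and 0.83. The macrophage list, not called, had 1.21 in BDIX, -0.07 in BDIV and -0.22 in the congenic. The sex chromosome (-0.43, 0.00536) and central nervous system glia lists (-0.59, 0.0209) had lower values, the latter with 0.73 in BDIX, -0.92 in BDIV and -1.96 in the congenic. All 8 were lost when the correlation was estimated (adjusted p = 0.741 with an estimated correlation for the ribosomal list and 0.709 for the other 7), and fry called 0 of 32. Without the BDIX male array the antigen presentation (adjusted p = 0.608), ribosomal (0.0846), complement (0.543) and mitochondrial lists (0.267) lost their calls, and without the BDIX female array the same 4 (0.568, 0.0892, 0.534 and 0.275) and the sex chromosome list (0.0584) did. In both fits the antigen presentation and ribosomal medians turned below 0 (-0.025 and -0.058). Without the congenic male array the erythrocyte (0.222) and central nervous system glia lists (0.364) lost theirs, without the congenic female array the same pair did (0.22 and 0.356), and without either BDIV array the glia list did (0.114). Proliferation kept its call in all 6 of these fits, which hold 3 distinct estimates of the sex difference. A list of 24 neutrophil and bone marrow genes, written after male and female values had been seen, had a median of 1.41 over 19 tested members. Of these, 13 were called adjusted over the list alone and 0 over all probes (unadjusted camera p = 0.134 with an estimated correlation). Since the list was chosen from these values, the 13 are no independent support.

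The remaining lists were past the threshold in none of the 4 comparisons. Their smallest camera adjusted p was 0.058 for the pituitary, 0.0652 for the skeletal muscle and 0.0706 for the macrophage, bone and cartilage, and interferon response lists, in each case for sex. It was 0.113 for perineurial cells, 0.278 for the Schwann lineage, adipocyte and ErbB, Ras and neurofibromin lists, 0.257 for pericytes, 0.312 for satellite glia and sex steroid response, 0.395 for xenobiotic and oxidative defence, 0.407 for DNA repair and 0.421 for lymphocytes and mast cells. Median, mean and test differed in sign for 19 of the 128 pairs of list and comparison, none of them called.

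Effects by sex were described by size, since 1 array per strain and sex leaves no spread for a test of the interaction. The congenic minus BDIX difference in males and that in females differed by at least 1 log2 unit for 1040 of 9756 probes, with the male effect higher for 429 and the female effect higher for 611. The 2 effects correlated across probes with a Pearson r of 0.56, and of the probes beyond 2-fold in both sexes 430 shared the sign and 12 did not. With detection on all 6 arrays required, 684 remained. The genes named by the size of their gap rest in part on arrays below detection, where only the least gap is given and their order is not established. In favour of males the gap was 2.24 for Sh3bgrl1, with least gaps of 2.17 for Vegp2, 1.87 for Zfp317, 1.79 for Cpne4, 1.76 for RatNP-3b, 1.54 for the neutrophil collagenase gene Mmp8, 1.48 for Retnlg, 1.404 for Lcn1 and 1.30 for Lipf and Ngp. In favour of females it was -4.90 for the myelin gene Mog, -4.30 for the pituitary precursor gene Pomc, -4.09 for the oligodendrocyte factor gene Olig1 and for S1pr5, -4.08 for Itih3, -3.99 for Rhoa, -3.70 for the thyrotropin gene Tshb and -3.58 for Epcam. The myelin gene Mobp and Thrsp had gaps in favour of females of at least 4.88 and 2.99 log2 units. By list, the sensory neuron median gap was 0.62, at the 100th percentile of 10000 random lists matched on intensity. The marrow list's gap was 1.56, also at the 100th percentile. That list was written after male and female values had been seen, so its percentile is no independent support. Of the 19 marrow genes 6 were detected on all 4 arrays, with a median gap of 1.35. Central nervous system glia (-2.96), pituitary (-2.17), macrophage (-1.72), antigen presentation (-0.72) and ribosomal protein (-0.63) lay at the 0th percentile. Sterol genes were lower than in BDIX in congenic males (median -0.80) and in congenic females (-1.15).

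For BDIV minus BDIX the male and female effects differed by at least 1 log2 unit for 872 of 10275 probes, with 257 higher in males and 615 higher in females, and a Pearson r of 0.75 across probes. Of the probes beyond 2-fold in both sexes, 960 shared the sign and 4 did not. Genes with gaps in favour of males were Sgk1 (2.16), the myelin transcription factor gene Egr2 (2.06), Ptpdc1 (1.84), Cyth3 (1.81), Cavin1 (1.80) and Ppm1l (1.59), with least gaps of 1.64 for Trarg1, 0.86 for Zfp319, 0.83 for Slc9a8 and 0.68 for Prl. Those in favour of females were Mog (-3.81), Pomc (-3.53), Olig1 (-3.46), Mobp (-3.13) and Igfbp3 (-3.02), with least gaps of 3.20 for Epcam, 2.41 for Thrsp, 2.37 for Pcdh20 and 1.97 for Defa5 and RatNP-3b. The neuronal difference was present in both sexes, with list medians of 1.16 in males and 1.07 in females, and the myelinating Schwann cell list was lower in both (-0.91 and -1.51). Both effects by sex share the BDIX pair, so a value peculiar to 1 BDIX pool enters each of them.

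**Figure D4:**
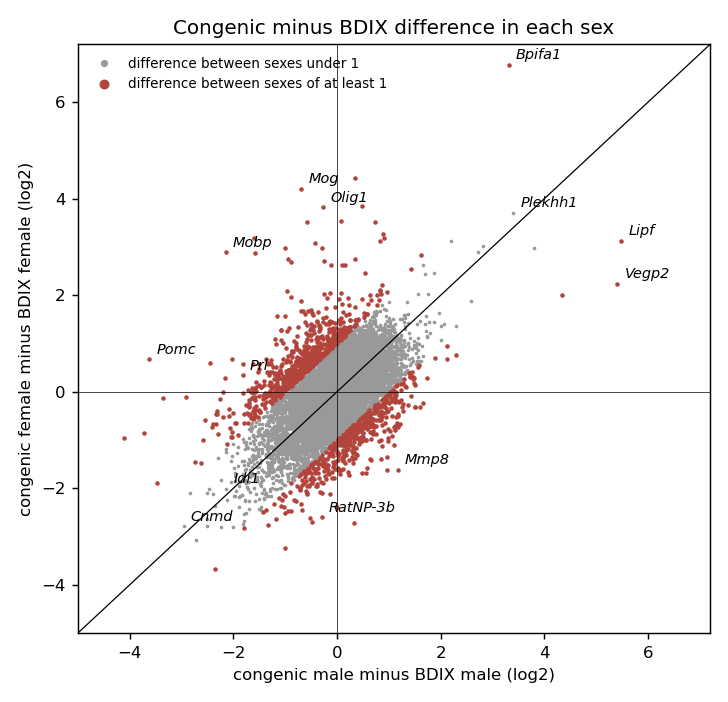
Congenic minus BDIX log2 difference in males (horizontal) against that in females (vertical) for the 10484 probes tested in the fit, with red points where the 2 differ by at least 1 and a line of equality. Plekhh1 and Cnmd lay near the line, Mog, Mobp and Olig1 far above it and Mmp8 below it.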

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

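Genes and lists whose effect had opposite signs in males and females stood out. The differences were not tested, since each strain and sex has 1 array. All values below are the effect in males minus the effect in females, in log2 units, for genes detected on all 4 arrays that enter them. List values are medians over such members.

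For congenic minus BDIX, the genes had the higher effect in females. They were Mog (-4.897), Pomc (-4.302), Olig1 (-4.094), S1pr5 (-4.091), Rhoa (-3.991), Tshb (-3.697) and Epcam (-3.577). Mog, a myelin protein of oligodendrocytes, differed from BDIX by -0.69 in congenic males and by 4.21 in congenic females. Among lists the median gap was 0.622 for sensory neuron and axon, 0.744 for erythrocyte and 1.354 for neutrophil and bone marrow genes. It was -1.762 for macrophage, -2.171 for pituitary, -0.716 for antigen presentation and -0.631 for ribosomal protein genes.

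For BDIV minus BDIX, Sgk1 (2.161), Egr2 (2.063), Ptpdc1 (1.842) and Cavin1 (1.803) had the higher effect in males. Mog (-3.812), Olig1 (-3.463) and Igfbp3 (-3.019) had it in females. Lists with opposite signs were macrophage (-1.587), antigen presentation (-0.794), xenobiotic and oxidative defence (-0.271) and ribosomal protein genes (-0.71).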

How the results depend on the processing

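The count for congenic versus BDIX, 1247, became 4316 with median scaling, 0 with the authors' processed values, 721 without a detection filter, 799 with only the 2 strains in the fit, 735 with background from all probes, and 581 to 3176 with 1 array left out. Congenic versus BDIV, 3880, became 5913 with median scaling, 2581 with the processed values and 1070 to 5793 with 1 array left out. BDIV versus BDIX, 2867, became 1325 with the processed values and 378 to 4404 with 1 array left out, and male versus female, 0, became 1 to 13. Probes called in both strains against BDIX in the same direction, 364, became 795 with median scaling, 0 with the processed values, 170 without a filter, 222 with background from all probes and 40 to 1634 with 1 array left out.

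Congenic effects by sex, 1040, became 459 with an offset of 50, 449 without background correction and 684 with detection on all 6 arrays. BDIV effects by sex, 872, became 473 and 474 with the first 2 of these.

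Lists called by camera (8, 7, 4 and 8) fell to 0 in all 4 comparisons with an estimated correlation and with fry, which have little power on 2 residual degrees of freedom. The processed values left 1 for congenic versus BDIX and 1 for congenic versus BDIV. With 1 array left out BDIV versus BDIX had 7 to 11 and congenic versus BDIX 4 to 7. For list antigen presentation in male versus female the median ran from -0.025 to 0.389, and for ribosomal protein from -0.058 to 0.268. Tjp1 (-0.012) and Itgb4 (-0.079) turned negative in congenic versus BDIV with median scaling, which moved the median of all probes to -0.644 and changed the sign of 443 calls.

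For the 100 genes with the smallest p, the fullest window had permutation p = 0.0257 and the chromosome test permutation adjusted p = 0.3465. For calls shared with BDIV the latter was 0.6761. Where the array left out belongs to neither of the strains compared, the difference itself is unchanged and only the estimate of the spread moves. The cause was not tested for the other shifts.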

Other observations

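Of 4 genes that stood higher on the congenic arrays, picked after their values were seen, 2 read higher in the male and 2 in the female pool. Lipf, a lipase of lingual glands and stomach, read 10.15 in the congenic male and 7.69 in the female pool, and the von Ebner gland lipocalin Lcn1 10.05 and 7.38. The airway protein Bpifa1 ran the other way, 8.34 and 11.81, as did Cyp2f4, a P450 of airway cells, at 6.41 and 7.15. No gene list or test covers them, and no dissection record is given in the sources used here.

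Some tests in this part were written after the results had been seen: that for compression of the congenic arrays, the 4 for marrow transcripts and the 2 for central nervous system glia. A comparator for the brightness test was also added after its value was seen, and the globin test was changed from a median to the largest single probe, and from both strains together to each strain, after its values were seen.

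The calls between congenic and BDIX may reflect the introgressed segment, the brightness of the congenic pair or a compression of its arrays. Calls gathered on 1 chromosome (permutation adjusted p = 0.0147), the outcome set beforehand for a donor segment. Where Mss4a lies was not used, so this excess cannot be credited to it. On that chromosome the calls shared with BDIV numbered 22 where 17.6 were expected (permutation adjusted p = 0.6761). The fullest window of 50 genes did not stand out (permutation p = 0.2687), and 92 calls where 65.7 were expected are a small part of 893. Calls shared with BDIV did not gather (permutation p = 0.9017), with 6 in the fullest window and a permuted mean of 6.43. The Mss4a interval itself was not tested and a few calls within it would go unseen, so a segment as their source is undecided. The congenic mean lay outside the range of BDIX and BDIV in 85.966% of calls (95% interval 83.9% to 87.8%). The bound of 50% set beforehand was too low, as 65.1% of probes not called lay outside too and BDIV did so in 92.8% of its own calls, so brightness or a shared hybridisation is undecided. The median of all probes of -0.52 under median scaling restates the dimness of these arrays in a scaling that the calls did not use, so compression is undecided too.

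Neutrophil and marrow transcripts were higher in BDIX and congenic males, by medians of 1.36 and 2.70, and could come from neutrophils or marrow in these pools. The lower value, 1.364, lay above all random lists. The list was written after male and female values had been seen, so this place is no independent support. In the congenic, Hba-a1, Hbb, Hba-a3 and Hbb-b1 rose by 0.076, 0.187, 0.037 and 0.658 in the male pool, at most 0.244 of the marrow median. Peripheral blood as the whole of the rise was set to give more. With 1 pair of pools and a test changed after its values were seen, it stays undecided there. Hba-a1 and Hbb also stood high, at 14.86 and 15.15 in the congenic male pool. The erythrocyte list rose by a median of 0.83, with 3 of its 5 genes in the marrow list. In BDIX males Hba-a3 and Hbb-b1 rose by 0.811 and 0.687, at most 0.594 of the marrow median, and Hba-a1 and Hbb fell by 0.124 and 0.448, so peripheral blood stays open in BDIX as well. A sex difference shared by the strains stays open too. The BDIV median of 0.03 lay at the 69.48th percentile, but only 6 of 19 members were detected on a BDIV array and there is 1 pair of pools. Marrow or neutrophil cells stay open as well, since the list was built from such genes, and inflammation in those animals was not analysed here.

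Central nervous system glia transcripts could come from the nerve root, where oligodendrocytes replace Schwann cells, if pools held unequal lengths of it. The list median lay outside the central range of random lists in 3 strains, the outcome set for this source after the values had been seen. Genes that move together leave that range whatever moves them, so the nerve root as the source is undecided. Males were higher in BDIX (0.727) and lower in BDIV (-0.92) and congenic (-1.96). With 1 pair of pools per strain this does not exclude a shared sex difference, which unequal root content of the BDIX pools would turn.

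The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. All 10 had at least the 0 calls of male versus female, which no split can fall below, and the highest other had 701. The 2 splits with 701 group the congenic pair with 1 BDIX array, and the other 7 had 0. With strain in the model those 2 set the BDIX male against the BDIX female array, 1 against 1 with the spread taken from the other strains.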
